A study of Xenopus laevis with 39 samples.

How the data were processed

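RNA sequencing of Xenopus laevis tissue covered 39 libraries in 13 groups of 3, and groups were taken from the sample titles. Per the labels, reads were demultiplexed with bcl2fastq 2.17.1.14, aligned with STAR 2.5 and counted per gene with featureCounts of Subread 1.5.0. The genome build and annotation are not given in the sources used here. Raw counts deposited by the authors, 37240 gene entries, were the input of every test. After 17 entries repeated with identical counts were dropped, 37223 genes were kept, and 1 further line was emptied for this work. The deposited normalised signal equals the raw count divided by 1 factor per library, and the deposited TPM values are scaled by gene length by the authors, and neither was tested. Columns name group and replicate but not the library number of the titles, so libraries were joined to groups only. Of the gene identifiers, 15693 end in .L, 11835 in .S, 9515 are unnamed models and 3409 are provisional loci, and 18180 match a symbol of the reference table.

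Library depth ran from 25.82 to 180.5 M counted reads (M, 1e6), with a median of 69.66 M, and the 10 most abundant genes took 2.89 to 9.13% of a library. The lowest Spearman correlation between 2 libraries of a group was 0.9578.

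Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Related groups were fitted together, with 1 model for the 7 nose groups (21 libraries), 1 for the 4 bulb groups (12 libraries), 1 for principal cavity and VNO (6 libraries) and 1 for noses and bulbs of the transection series (24 libraries), the last for tissue and interaction tests. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled with TMM factors and tested with the edgeR quasi-likelihood test with robust dispersion. P-values were adjusted by the Benjamini-Hochberg procedure within each comparison, and genes at an adjusted p under 0.05 were called. Errors of log2 fold changes are standard errors derived from the F statistic of that fit. Counts per megaread (CPM) use TMM-scaled library sizes, and levels of lists are means of log2 CPM after 1 was added. Folds against a group without reads are given as lower bounds, from a floor of 3 counts over the group. Tests on simulated data of known change, built on the measured means, depths and dispersions, recovered 82.5% of 4-fold and 56.9% of 2-fold changes in noses at 2 days with 4.64% false calls. For principal cavity against VNO the shares were 55.9% and 8.18%, with 12.6% false calls.

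Gene lists, comparisons, their tests and most alternatives were set before the data were examined, and tests and alternatives chosen later are stated as such below. The 33 lists cover olfactory and vomeronasal transduction, immature neurons, progenitor factors, epithelial cells, cell cycle, motile cilia, leukocytes, inflammation, interferon response, apoptosis, axon injury, immediate early genes, ATF4 response, chaperones, synapses, bulb markers, myelin, glia, thyroid hormone response, mucus, xenobiotic metabolism, matrix, cartilage, muscle, erythroid cells, endothelium, cholesterol synthesis, ribosomal proteins, the respiratory chain and 3 receptor families. Symbols were matched without homeolog suffix and copy number, so both homeologs count as members and are not independent. The name pattern of vomeronasal receptor families matched 0 genes, since it misses symbols such as vn2r1p.L, and trace amine receptors 2, under the minimum of 5, and were not tested, and the olfactory receptor family matched 15. Lists were tested with camera at a preset correlation of 0.01, with the Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the data and with fry. Members adjusted over the list alone are counted beside the calls over all genes.

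Named genes follow a rule fixed in advance. It takes, per comparison, up to 6 higher and 6 lower called genes of largest fold change with a mean of at least 5 CPM in the higher group and libraries that do not overlap, which chance gives in 10% of genes at 3 against 3. To these come up to 4 called members of each list described, with at least 1 CPM, and a fixed set of marker genes. Values of gng13.L against controls and of umodl1.L against 2 days in noses at 7 weeks, of mx2.L in control noses, all values of single libraries, and the shared-control simulation of the transection comparisons were added after the data had been seen. Genes whose call ended, or whose log2 value moved by more than 1.5 times, when 1 library was left out, and genes whose call ended with another test, model or with homeologs summed, were passed over as examples after this had been seen, except where that is stated. Those passed over for the test or model were, among others, mmp8.S and top2a.L in noses at 2 days and actc1.L at the amino acid dose 1000. A few genes that meet the rule are not reported here.

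Alternatives were DESeq2 size factors (RLE) in edgeR, the Wald test of DESeq2 1.42.0, no low-count filter, all 39 libraries in 1 model, homeolog counts summed, each library left out in turn, a replicate block for principal cavity and VNO, and, for the shared effect of the amino acid doses, genes of at least 5 CPM. Left out were single reads and splice forms, which counts per gene do not hold.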

Results

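Messenger RNA was sequenced from the olfactory organ and the olfactory bulb of the frog Xenopus laevis, in 13 groups of 3 libraries each (39 libraries). The groups were noses of control larvae and of adults (stage 66), the larval principal cavity and the larval vomeronasal organ (VNO) dissected apart, and control larval bulbs. Noses and bulbs were also taken 2 days, 1 week and 7 weeks after the larval olfactory nerve had been cut. Further larval noses were taken 5 h into an amino acid treatment with the dose number 200 or 1000 (the unit in the titles is incomplete). Each library held between 25.82 and 180.5 M counted reads (median 69.66 M), and between 31323 and 36646 of 37223 genes had at least 1 read. Gene names carry the suffix .L or .S for the 2 subgenomes of this species, and how reads of near-identical copies were shared out between them was not examined. A value in parentheses after a gene is its log2 fold change ± SE with n = 3 libraries per group, followed, where it moved by more than 1, by the value with both homeologs summed. Levels are mean counts per megaread (CPM) ± SD, and p-values measure only the spread between these libraries, since the labels do not say whether libraries of a group came from separate animals.

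Adult noses were compared with larval noses to ask how the organ differs between life stages (n = 3 libraries per group). The enamel protein gene enam.L (9.83 ± 1.44) was among large increases, together with keratin krt6.L (9.44 ± 1.64) and crisp3.L (8.92 ± 0.94). Without control nose library 1 these were 11.59, 13.01 and 10.68. Other keratins fell, among them krt2l.S (-10.56 ± 0.46), from 351 to 0.225 CPM, krt75.L (-8.09 ± 0.33) and krt15.L (-7.34 ± 0.44), as did uromodulin umod.2.L (-9.99 ± 1.1). Of the genes of olfactory transduction and mature receptor neurons, 18 of 38 rose, 8 fell and 12 neither (18 and 8 adjusted over the list alone), with stoml3.S (6.17 ± 0.30, 0.90 summed) and the cyclic nucleotide-gated channel subunit cnga2.L (2.32 ± 0.21). Camera on the olfactory transduction list gave adjusted p = 0.011, and adjusted p = 0.85 with an estimated correlation. Proneural genes were lower: in the list of neuronal progenitor factors 7 of 74 rose, 33 fell and 34 neither (8 and 38 adjusted over the list alone), including neurod4.L (-2.76 ± 0.30) and neurog1.L (-2.56 ± 0.50). Camera on the progenitor list gave adjusted p = 0.00029, and adjusted p = 0.55 with an estimated correlation. Cell cycle genes fell almost throughout, and 2 of 144 rose, 129 fell and 13 neither (2 and 133 adjusted over the list alone), with aurkb.L (-2.52 ± 0.42), plk1.L (-2.48 ± 0.47) and top2a.L (-1.94 ± 0.45). Camera on the cell cycle list gave adjusted p = 1.9e-23, and adjusted p = 0.46 with an estimated correlation. Among thyroid hormone response genes, which act in frog metamorphosis, 22 of 56 rose, 13 fell and 21 neither (22 and 13 adjusted over the list alone). Camera on the thyroid hormone list gave adjusted p = 0.00044, and adjusted p = 0.41 with an estimated correlation. Examples were the hormone-induced factors thibz.S (6.42 ± 0.79) and klf9.L (2.38 ± 0.35), the hormone-inactivating enzyme dio3.L (3.77 ± 0.33) and crhbp.S (7.44 ± 0.44, 4.79 summed). Mucus and secretory genes rose (26 of 46 rose, 7 fell and 13 neither, 26 and 9 adjusted over the list alone), with muc19.L (5.17 ± 0.79) and aqp5.S (4.27 ± 0.36) against a fall of itln1.S (-4.35 ± 0.22). Camera on the mucus list gave adjusted p = 0.0025, and adjusted p = 0.41 with an estimated correlation. Interferon and antigen presentation genes were lower (2 of 48 rose, 37 fell and 9 neither, 2 and 37 adjusted over the list alone), for example ifit5.L (-2.73 ± 0.27) and tap1.L (-2.57 ± 0.38). Camera on the interferon list gave adjusted p = 4.7e-09, and adjusted p = 0.46 with an estimated correlation. Cholesterol synthesis genes were lower too (1 of 52 rose, 37 fell and 14 neither, 1 and 38 adjusted over the list alone), such as msmo1.S (-2.33 ± 0.40). Camera on the cholesterol list gave adjusted p = 5.3e-08, and adjusted p = 0.41 with an estimated correlation. The GABA synthesis gene gad2.L (4.19 ± 0.80), at 3.82 CPM, and the GABA vesicle transporter slc32a1.S (5.22 ± 1.07) were also higher in adult noses. In the edgeR test 7759 genes were higher and 7708 lower in adults of 34151 tested. Larval growth and metamorphosis separate these groups, so stage and tissue makeup differ together.

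The larval principal cavity was set against the larval VNO to ask which transcripts divide the 2 chambers (n = 3 per group). The principal cavity carried the ciliated-neuron transduction genes, with cnga2.L (5.44 ± 0.72) at 13.7 ± 5.27 against 0.293 ± 0.232 CPM, the G protein subunits gng13.L (4.58 ± 0.60) and gng13.S (4.57 ± 0.60), and the transcription factor lhx2.S (4.36 ± 0.37, 1.91 summed). Within the olfactory transduction list 11 of 38 were higher, 0 lower and 27 neither (15 and 2 adjusted over the list alone). The olfactory transduction list had camera adjusted p = 7.4e-06, and adjusted p = 0.45 with an estimated correlation. Annotated olfactory receptor genes showed the same direction, and 12 of 13 were higher, 0 lower and 1 neither (13 and 0 adjusted over the list alone), including or5i1.L (4.60 ± 0.58) and or4e2.L (6.43 ± 1.1), the latter 9.08 without VNO library 3. Camera on the olfactory receptor list gave adjusted p = 3.1e-11, and adjusted p = 0.23 with an estimated correlation. Other genes higher in the principal cavity were casr.L (5.42 ± 0.45), htr3c.L (4.81 ± 0.64), chrd.1.L (5.01 ± 0.78) and olig2.L (5.0 ± 0.84). VNO libraries were higher in the potassium channel kcnk12.S (-5.88 ± 0.30), cpne4.S (-5.52 ± 0.37), the transcription factors mef2c.L (-5.10 ± 0.25) and sox1.S (-4.97 ± 0.39), somatostatin sst.L (-4.98 ± 0.42), calretinin calb2.L (-2.28 ± 0.29) and the G protein subunit gng8.S (-2.24 ± 0.26). The list of vomeronasal transduction was mixed, and 4 of 23 were higher, 8 lower and 11 neither (4 and 9 adjusted over the list alone). Camera on the vomeronasal transduction list gave adjusted p = 0.044, and adjusted p = 0.74 with an estimated correlation. Motile cilia genes were higher in the principal cavity (31 of 67 were higher, 2 lower and 34 neither, 50 and 2 adjusted over the list alone), with ropn1l.L (1.39 ± 0.21) and foxj1.L (1.24 ± 0.20), although dnah11.L (-2.84 ± 0.21) was lower. Camera on the cilia list gave adjusted p = 2.6e-09, and adjusted p = 0.74 with an estimated correlation. Detoxification genes such as gsta1.L (2.85 ± 0.33, 1.38 summed) and cyp2a13.L (2.70 ± 0.20) were higher as well (19 of 49 were higher, 6 lower and 24 neither, 22 and 7 adjusted over the list alone). Camera on the detoxification list gave adjusted p = 0.00018, and adjusted p = 0.23 with an estimated correlation. Endothelial genes were higher alike (17 of 61 were higher, 0 lower and 44 neither, 32 and 0 adjusted over the list alone), with cdh5.S (1.95 ± 0.35). Camera on the endothelial list gave adjusted p = 5.6e-09, and adjusted p = 0.23 with an estimated correlation. Chaperones of the endoplasmic reticulum were lower in the principal cavity (1 of 66 were higher, 23 lower and 42 neither, 1 and 28 adjusted over the list alone), for instance hsp90b1.L (-2.23 ± 0.24) and manf.S (-2.30 ± 0.26). Camera on the chaperone list gave adjusted p = 5.6e-09, and adjusted p = 0.23 with an estimated correlation. Of 31396 genes tested, 2719 were higher and 2049 lower in the principal cavity by the edgeR test. These groups spread widely: top2a.L, a proliferation gene, stood at 47.4, 154 and 10.1 CPM in the principal cavity libraries, and keratin krt2l.S at 255, 1.32 and 4.35 CPM in the VNO libraries. The count of 4768 genes fell to 1999, 2646 and 2467 without principal cavity library 1, principal cavity library 3 and VNO library 2, and was 4840 without principal cavity library 3 and VNO library 1 together. With all 39 libraries in 1 model it was 13486 (8138 higher and 5348 lower).

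Control larval noses and bulbs differed in most genes, which gives the tissue markers for the transection series (n = 3 per group). Noses carried the vomeronasal receptor gene vn2r1p.L (12.12 ± 0.71), gng8.S (11.71 ± 0.61, 8.05 summed), casr.L (11.43 ± 0.85) and epithelial genes such as psca.L (11.11 ± 0.60) and krt15.L (11.10 ± 0.85). Among basal and epithelial support genes 48 of 54 were higher, 3 lower and 3 neither (48 and 3 adjusted over the list alone), with the hemidesmosome collagen col17a1.L (10.79 ± 1.02). Camera on the epithelial list gave adjusted p = 8.2e-14, and adjusted p = 0.066 with an estimated correlation. Motile cilia genes were on the nose side (64 of 69 were higher, 3 lower and 2 neither, 65 and 3 adjusted over the list alone), with tekt3.S (5.66 ± 0.15). The cilia list had camera adjusted p = 6e-23, and adjusted p = 0.013 with an estimated correlation. Cartilage and bone genes were there too (49 of 59 were higher, 2 lower and 8 neither, 49 and 2 adjusted over the list alone), with matn1.L (10.45 ± 0.48). Camera on the cartilage list gave adjusted p = 4.3e-16, and adjusted p = 0.039 with an estimated correlation. Bulbs carried the forebrain factors neurod6.L (-13.42 ± 0.63) and neurod2.S (-12.72 ± 0.72). No nose library had a read of zic4.S or nkx2-1.L, which were at least 2640-fold and 1760-fold higher in bulbs (floor of 3 counts over the nose group). Synaptic and central neuron genes were lower in noses, and 2 of 102 were higher, 99 lower and 1 neither (2 and 100 adjusted over the list alone), including the GABA synthesis genes gad1.1.L (-11.43 ± 0.84, -9.59 summed) and gad2.L (-10.46 ± 0.65). Camera on the synaptic list gave adjusted p = 2.8e-27, and adjusted p = 0.045 with an estimated correlation. The olfactory bulb cell markers followed (17 of 74 were higher, 52 lower and 5 neither, 17 and 52 adjusted over the list alone), with npy.S (-11.89 ± 0.86) and lhx1.L (-11.75 ± 0.74). Camera on the bulb marker list gave adjusted p = 2.1e-08, and adjusted p = 0.066 with an estimated correlation. By the edgeR test 13699 genes were higher in noses and 12111 in bulbs, of 34508 tested.

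Noses taken 2 days after nerve transection had lost part of the receptor neuron transcripts and gained those of phagocytes, relative to control noses (n = 3 per group). The G protein subunit gng13.L (-1.92 ± 0.23) stood at 40.2 ± 13.9 against 152 ± 18.4 CPM, and umodl1.L (-2.03 ± 0.25), made by olfactory neurons, at 79.5 ± 32.9 against 325 ± 64.4 CPM. Of the olfactory transduction genes, 1 of 38 rose, 19 fell and 18 neither (1 and 21 adjusted over the list alone). For olfactory transduction genes camera gave adjusted p = 1.2e-07, and adjusted p = 0.38 with an estimated correlation. Vomeronasal transduction genes fell as well (0 of 23 rose, 9 fell and 14 neither, 0 and 10 adjusted over the list alone), with gng8.S (-1.68 ± 0.28) and calb2.S (-1.53 ± 0.24). The vomeronasal transduction list had camera adjusted p = 6.9e-06, and adjusted p = 0.34 with an estimated correlation. Also lower were casr.L (-3.93 ± 0.48), vn2r1p.L (-2.96 ± 0.40), htr3c.L (-3.21 ± 0.29) and rgs20.S (-3.03 ± 0.27). Macrophage and leukocyte genes rose: 44 of 103 rose, 0 fell and 59 neither (54 and 1 adjusted over the list alone), among them the myeloid adaptor tyrobp.S (2.00 ± 0.22), the phagosomal transporter slc11a1.L (1.56 ± 0.21), gpnmb.L (1.48 ± 0.14) and trem2.S (1.42 ± 0.17). Camera on the leukocyte list gave adjusted p = 1.6e-14, and adjusted p = 0.097 with an estimated correlation. Inflammatory mediators moved both ways (14 of 78 rose, 4 fell and 60 neither, 16 and 4 adjusted over the list alone), with steap4.L (2.44 ± 0.30) and hmox1.S (1.81 ± 0.21, 0.80 summed) up. Camera on the inflammatory list gave adjusted p = 0.00037, and adjusted p = 0.71 with an estimated correlation. The other large increases were art5.L (3.02 ± 0.20), the myelin lipid carrier pmp2.S (2.94 ± 0.19, 0.73 summed), tagln.S (2.54 ± 0.43) and complement c1s.L (2.31 ± 0.23). Of the immature neuron genes 4 rose and 13 fell of 59, 5 and 15 adjusted over the list alone. Proliferation genes were lower in these noses, and 0 of 144 rose, 117 fell and 27 neither (1 and 124 adjusted over the list alone), with aurkb.L (-2.09 ± 0.42) and plk1.L (-1.87 ± 0.46). The cell cycle list had camera adjusted p = 1.8e-34, and adjusted p = 0.34 with an estimated correlation. Cholesterol synthesis genes fell too (1 of 52 rose, 35 fell and 16 neither, 1 and 39 adjusted over the list alone), such as msmo1.S (-1.73 ± 0.39). The cholesterol list had camera adjusted p = 3.6e-16, and adjusted p = 0.083 with an estimated correlation. In the edgeR test 3284 genes were higher and 3615 lower, of 34151 tested. The majority turned with RLE factors (53.8% higher), the Wald test (53.4%) and all 39 libraries in 1 model (54.2%). The count of 6899 fell to 3888 without library 3 of this group, to 4411 without its library 2 and to 4336 without control nose library 3.

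**Figure D1:**
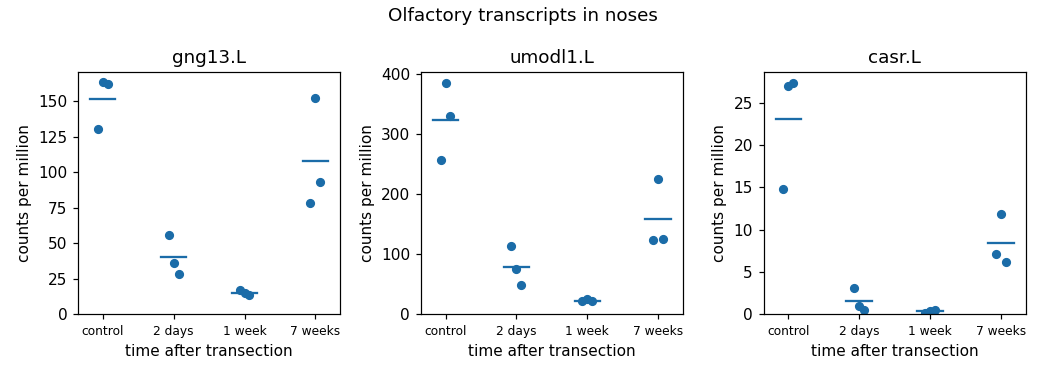
CPM (y axes, linear) of 3 olfactory transcripts in control larval noses and 2 days, 1 week and 7 weeks after nerve transection (x axes). Points are the 3 libraries of each group and bars their mean, which for gng13.L was 152 in controls, 40.2 at 2 days, 15.2 at 1 week and 108 at 7 weeks.

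At 1 week the receptor neuron transcripts of the nose were lower still against controls (n = 3 per group). Levels of gng13.L (-3.32 ± 0.24) and umodl1.L (-3.83 ± 0.27) were 15.2 ± 1.65 against 152 ± 18.4 CPM and 22.9 ± 1.86 against 325 ± 64.4 CPM. Further, cnga2.L (-2.54 ± 0.23), casr.L (-6.03 ± 0.56, -4.88 summed), vn2r1p.L (-4.94 ± 0.45) and s100z.S (-4.35 ± 0.31) fell along with them. In the olfactory transduction list 1 of 38 rose, 24 fell and 13 neither (1 and 25 adjusted over the list alone). Camera on the olfactory transduction list gave adjusted p = 5.7e-12, and adjusted p = 0.28 with an estimated correlation. Of the annotated olfactory receptors 0 of 14 rose, 9 fell and 5 neither (1 and 9 adjusted over the list alone), for example or5i1.L (-3.18 ± 0.41). The olfactory receptor list had camera adjusted p = 0.00092, and adjusted p = 0.33 with an estimated correlation. Vomeronasal transduction genes fell in the same way (1 of 23 rose, 15 fell and 7 neither, 1 and 15 adjusted over the list alone). For vomeronasal transduction genes camera gave adjusted p = 6.1e-06, and adjusted p = 0.28 with an estimated correlation. The neurogenic factors neurog1.L (-2.20 ± 0.50) and neurod1.L (-1.28 ± 0.29) fell. The progenitor list as a whole was mixed (15 of 74 rose, 32 fell and 27 neither, 16 and 32 adjusted over the list alone). The progenitor list had camera adjusted p = 0.0073, and adjusted p = 0.65 with an estimated correlation. Leukocyte genes were high again, and 48 of 103 rose, 6 fell and 49 neither (49 and 6 adjusted over the list alone), with trem2.S (1.90 ± 0.17), apoe.L (1.80 ± 0.27, 0.72 summed) and ncf1.S (1.78 ± 0.23). The leukocyte list had camera adjusted p = 8.6e-08, and adjusted p = 0.28 with an estimated correlation. A further set rose strongly: the matrix protease mmp7.S (4.96 ± 0.50, 1.23 summed), neuregulin nrg3.S (4.53 ± 0.60), the vitamin D hydroxylase cyp24a1.L (4.47 ± 0.35), mpp2.S (4.13 ± 0.37), piwil1.L (3.80 ± 0.17) and olfm2.S (3.58 ± 0.36). Cell cycle genes fell (3 of 144 rose, 124 fell and 17 neither, 4 and 125 adjusted over the list alone). For cell cycle genes camera gave adjusted p = 7.6e-33, and adjusted p = 0.28 with an estimated correlation. Globin hbg2.L (-4.12 ± 0.90) fell, and so did the matrix list (11 of 91 rose, 36 fell and 44 neither, 12 and 39 adjusted over the list alone), with col3a1.S (-2.48 ± 0.40). Camera on the matrix list gave adjusted p = 0.016, and adjusted p = 0.97 with an estimated correlation. Of the genes called at 2 days against controls, 2789 of 3284 higher and 3229 of 3615 lower ones were called with the same sign at 1 week, beside 592 and 782 for independent lists. These comparisons share their controls, and in their 9 libraries the covariance of log2 fold changes was 0.44, against at most 0.06 in 20 simulated pairs of unchanged groups sharing the controls. In all 6158 genes were higher and 7385 lower by the edgeR test, of 34151.

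At 7 weeks some receptor neuron transcripts had come back part of the way, while many others had moved further from the controls (n = 3 per group). Against noses at 2 days, gng13.L (1.43 ± 0.23) and umodl1.L (1.00 ± 0.24) were higher. The olfactory transduction list as a whole went both ways (median -0.16, mean 0.04): 7 of 38 rose, 11 fell and 20 neither (7 and 11 adjusted over the list alone). The olfactory transduction list had camera adjusted p = 0.66, and adjusted p = 0.92 with an estimated correlation. Against controls gng13.L was at -0.49 ± 0.22 (adjusted p = 0.076), not past the threshold, but without library 2 of the 7-week group at -0.78, past it. Against controls the same list was still lower (4 of 38 rose, 23 fell and 11 neither, 4 and 24 adjusted over the list alone), with gnao1.L (-1.93 ± 0.34) and slc17a6.L (-2.51 ± 0.23). For olfactory transduction genes camera gave adjusted p = 0.00064, and adjusted p = 0.6 with an estimated correlation. Of the olfactory receptor genes 2 rose and 3 fell of 14 (2 and 3 adjusted over the list alone). Immature neuron genes were far lower than in controls, and 3 of 59 rose, 48 fell and 8 neither (3 and 50 adjusted over the list alone), with the tubulins tubb3.S (-3.45 ± 0.25) and tubb2b.S (-3.07 ± 0.29) and dpysl5.L (-3.41 ± 0.38). Camera on the immature neuron list gave adjusted p = 1.3e-18, and adjusted p = 0.25 with an estimated correlation. Progenitor factors fell likewise (7 of 74 rose, 34 fell and 33 neither, 8 and 34 adjusted over the list alone), with neurod4.L (-4.57 ± 0.36) and neurog1.L (-4.16 ± 0.62). For progenitor genes camera gave adjusted p = 1.1e-05, and adjusted p = 0.46 with an estimated correlation. Connective tissue genes were lower: 12 of 91 rose, 55 fell and 24 neither (13 and 58 adjusted over the list alone) in the fibroblast and matrix list, with collagen col1a1.L (-5.17 ± 0.36). The matrix list had camera adjusted p = 2.1e-09, and adjusted p = 0.6 with an estimated correlation. In the cartilage and bone list 6 of 59 rose, 34 fell and 19 neither (6 and 36 adjusted over the list alone), with col2a1.S (-5.49 ± 0.69). The cartilage list had camera adjusted p = 2.8e-07, and adjusted p = 0.6 with an estimated correlation. Keratin krt2l.S (-6.57 ± 0.38) and globin hbg2.L (-6.20 ± 1.00) fell, whereas the thyroid hormone and glucocorticoid target klf9.L (4.29 ± 0.38) rose from 11.7 to 228 CPM. Stanniocalcin stc2.L (4.51 ± 0.21) and ddit4.S (3.66 ± 0.50) rose in the amino acid and ATF4 response list, where 29 of 72 rose, 18 fell and 25 neither (29 and 18 adjusted over the list alone). Camera on the ATF4 list gave adjusted p = 0.035, and adjusted p = 0.66 with an estimated correlation. Genes of cytosolic ribosomal proteins were higher as a block (105 of 107 rose, 0 fell and 2 neither, 106 and 0 adjusted over the list alone), for example rpl38.S (2.57 ± 0.25). Camera on the ribosomal list gave adjusted p = 3.6e-63, and adjusted p = 0.25 with an estimated correlation. Other increases were nrg3.S (6.87 ± 0.64), mmp7.S (5.99 ± 0.51, 1.39 summed), slurp1l.S (5.38 ± 0.58) and slc38a4.S (5.25 ± 0.54, 1.96 summed). The central neuron gene gad1.1.L (5.99 ± 0.98, 4.17 summed) rose, at 11.7, 4.03 and 0.349 CPM in the 3 libraries. By the edgeR test 7419 genes were higher and 9150 lower than in controls of 34151 tested.

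Between 2 days and 7 weeks the phagocyte and antiviral transcripts of the nose declined (n = 3 per group). In the leukocyte list 3 of 103 rose, 52 fell and 48 neither (4 and 55 adjusted over the list alone), with apoe.S (-2.14 ± 0.23) and cxcr4.S (-1.85 ± 0.13). For leukocyte genes camera gave adjusted p = 2e-08, and adjusted p = 0.29 with an estimated correlation. In the interferon list 2 of 48 rose, 37 fell and 9 neither (3 and 37 adjusted over the list alone), with tapbp.S (-2.03 ± 0.25). The interferon list had camera adjusted p = 6.9e-13, and adjusted p = 0.29 with an estimated correlation. Immature neuron genes were lower at 7 weeks (2 of 59 rose, 40 fell and 17 neither, 3 and 41 adjusted over the list alone), including stmn2.L (-3.11 ± 0.28) and gap43.L (-1.94 ± 0.15). The immature neuron list had camera adjusted p = 5.1e-20, and adjusted p = 0.29 with an estimated correlation. Myelin gene mpz.S (-2.96 ± 0.25), of peripheral nerve sheaths, fell from 83.4 to 10.7 CPM, in a list where 8 of 41 rose, 19 fell and 14 neither (9 and 19 adjusted over the list alone). Camera on the myelin list gave adjusted p = 0.045, and adjusted p = 0.56 with an estimated correlation. Genes of the respiratory chain rose (65 of 132 rose, 0 fell and 67 neither, 68 and 0 adjusted over the list alone), such as ndufb1.S (1.52 ± 0.29). Camera on the respiratory list gave adjusted p = 1e-08, and adjusted p = 0.69 with an estimated correlation. Large increases included atp12a-like.1.L (5.32 ± 1.41), which was 3.58 without library 1 at 7 weeks, btg5.L (4.44 ± 0.71), zbtb16.S (4.05 ± 0.55) and msmb.3.L (3.99 ± 0.44). The edgeR test gave 6404 higher and 7336 lower genes at 7 weeks, of 34151, and 4627 and 8146 (36.2% higher) with all 39 libraries in 1 model.

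In the bulb antiviral and phagocyte genes rose at 2 days and genes of dividing cells fell, relative to control bulbs (n = 3 per group). No uncut bulbs are labelled as matched in time, so at each time loss of input cannot be told apart from age or collection. Of the interferon response and antigen presentation genes 43 of 48 rose, 1 fell and 4 neither (43 and 3 adjusted over the list alone): the antiviral GTPase mx2.L (4.98 ± 0.45) went from 0.447 to 13.9 CPM, with rsad2.S (4.27 ± 0.40) and ifit5.L (4.03 ± 0.43). For interferon genes camera gave adjusted p = 4.9e-28, and 0.054 with an estimated correlation. Leukocyte genes rose in the same libraries (72 of 99 rose, 4 fell and 23 neither, 75 and 5 adjusted over the list alone), among them the lipid carrier apoe.L (3.93 ± 0.35, 1.64 summed), the pan-leukocyte phosphatase ptprc.S (2.82 ± 0.28), the microglial receptor p2ry12.L (2.55 ± 0.36) and gpnmb.L (2.5 ± 0.23). Camera on the leukocyte list gave adjusted p = 2.9e-18, and 0.091 with an estimated correlation. Inflammatory mediators followed (46 of 74 rose, 3 fell and 25 neither, 47 and 3 adjusted over the list alone), with irg1.S (2.91 ± 0.44), nfkbiz.S (2.78 ± 0.30) and tnf.L (2.30 ± 0.34). The inflammatory list had camera adjusted p = 1.8e-09, and 0.13 with an estimated correlation. Without control bulb library 3 irg1.S was 4.07. Cell cycle genes fell, and 1 of 141 rose, 133 fell and 7 neither (1 and 134 adjusted over the list alone), including the replication helicase genes mcm6.2.S (-3.89 ± 0.22) and mcm5.L (-3.58 ± 0.20). Camera on the cell cycle list gave adjusted p = 2.3e-88, and 0.033 with an estimated correlation. Proneural neurog1.L (-2.16 ± 0.27) and neurod4.S (-1.58 ± 0.16) fell in the progenitor list (11 of 75 rose, 45 fell and 19 neither, 12 and 45 adjusted over the list alone). Camera on the progenitor list gave adjusted p = 3.7e-06, and 0.2 with an estimated correlation. Serine synthesis gene psph.S (-3.31 ± 0.39) and chac1.L (-3.02 ± 0.62) fell in the ATF4 list (11 of 72 rose, 41 fell and 20 neither, 11 and 41 adjusted over the list alone). The ATF4 list had camera adjusted p = 3.7e-07, and 0.46 with an estimated correlation. Glial genes were mixed: radial glial fabp7.L (-1.94 ± 0.27) fell and aldh1l1.L (2.22 ± 0.25) rose (4 of 51 rose, 22 fell and 25 neither, 4 and 22 adjusted over the list alone). Camera on the glial list gave adjusted p = 0.0058, and 0.2 with an estimated correlation. The protease gene sppl2b.L (10.33 ± 0.32, 2.77 summed) was near 0 in every control bulb (0.135, 0.361 and 0.206 CPM) and at 314, 373 and 268 CPM at 2 days. Epithelial genes, which were near 0 in control bulbs, were also present at 2 days, with krt15.L (7.13 ± 0.91), col17a1.L (6.27 ± 1.13) and krt2l.S (5.76 ± 0.75, 2.89 summed) at 8.59, 20 and 32 CPM (20 of 51 rose, 2 fell and 29 neither, 20 and 2 adjusted over the list alone). The epithelial list had camera adjusted p = 0.0015, and adjusted p = 0.54 with an estimated correlation. By the edgeR test 6834 genes were higher and 7818 lower of 31701 tested.

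**Figure D2:**
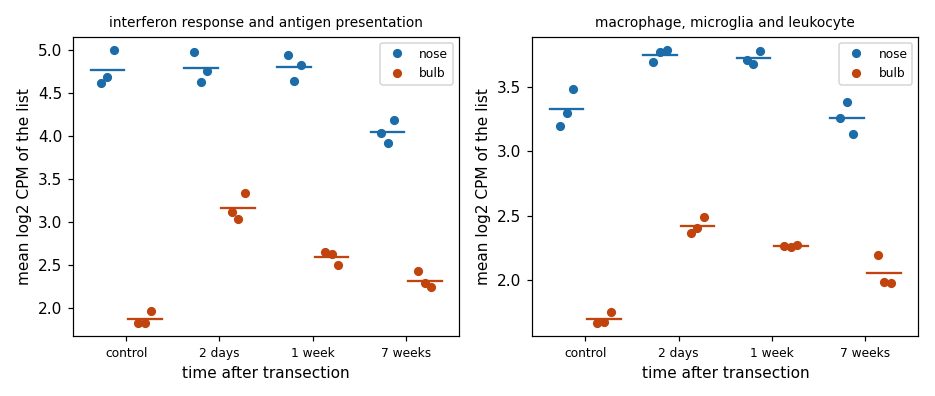
Mean log2 CPM over the members of the interferon and antigen presentation list and of the macrophage, microglia and leukocyte list (y axes) in noses and bulbs of control larvae and at 3 times after nerve transection (x axes). Points are libraries and bars group means, and in bulbs 43 interferon genes and 72 leukocyte genes rose at 2 days.

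At 1 week the bulb still carried the immune transcripts, and its cell cycle genes were lower again against controls (n = 3 per group). In the interferon list 35 of 48 rose, 4 fell and 9 neither (36 and 4 adjusted over the list alone), with rsad2.S (4.27 ± 0.40, 3.15 summed) and mhc1a.L (2.77 ± 0.30). Camera on the interferon list gave adjusted p = 5.4e-07, and 0.3 with an estimated correlation. In the leukocyte list 70 of 99 rose, 5 fell and 24 neither (72 and 5 adjusted over the list alone), with apoe.L (3.58 ± 0.35, 1.34 summed) and cd74.S (2.23 ± 0.20). The leukocyte list had camera adjusted p = 4.7e-08, and 0.23 with an estimated correlation. The acute-phase factor cebpd.L (3.76 ± 0.39) and complement cfb.L (2.92 ± 0.36) rose among inflammatory mediators (32 of 74 rose, 3 fell and 39 neither, 32 and 3 adjusted over the list alone). For inflammatory genes camera gave adjusted p = 0.00049, and 0.33 with an estimated correlation. Cell cycle genes fell (2 of 141 rose, 130 fell and 9 neither, 2 and 131 adjusted over the list alone), with kif20a.S (-6.28 ± 0.28, -4.89 summed), ccna2.L (-6.28 ± 0.25) and top2a.L (-5.75 ± 0.43). The cell cycle list had camera adjusted p = 4.7e-95, and 0.032 with an estimated correlation. Immature neuron genes were lower (4 of 59 rose, 41 fell and 14 neither, 4 and 43 adjusted over the list alone), such as tubb2b.L (-2.69 ± 0.18). For immature neuron genes camera gave adjusted p = 6e-08, and adjusted p = 0.15 with an estimated correlation. Cholesterol synthesis fell over nearly all measured steps (1 of 52 rose, 45 fell and 6 neither, 1 and 45 adjusted over the list alone), with msmo1.L (-4.32 ± 0.23) and sqle.L (-3.22 ± 0.13). For cholesterol genes camera gave adjusted p = 3.4e-41, and adjusted p = 0.04 with an estimated correlation. Neural stem cell intermediate filament nes.S (-3.00 ± 0.19) fell and aldh1l1.L (2.86 ± 0.26) rose. Other large increases were sppl2b.L (11.08 ± 0.33, 3.42 summed), serine dehydratase sds.S (5.89 ± 0.69), methionine enzyme mat1a.S (4.12 ± 0.18, 2.85 summed) and the germ-cell genes morc1.S (4.27 ± 0.19) and sycp2.S (4.14 ± 0.29, 2.5 summed). Of the genes called at 2 days, 5773 of 6834 higher and 6919 of 7818 lower genes were called with the same sign at 1 week, beside 1844 and 2273 for independent lists. The control bulbs are shared, and the covariance was 0.85 in these 9 libraries, against at most 0.03 in 20 simulated pairs of unchanged groups. The edgeR test called 8552 genes higher and 9215 lower, of 31701.

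Bulbs at 7 weeks carried acute-phase and immune transcripts and few of dividing cells against control bulbs (n = 3 per group). Inflammatory mediators rose (48 of 74 rose, 3 fell and 23 neither, 48 and 3 adjusted over the list alone), with cebpd.L (5.31 ± 0.42) at 451 ± 154 against 11.3 ± 5.24 CPM and cfb.L (4.63 ± 0.39). Camera on the inflammatory list gave adjusted p = 6.4e-06, and adjusted p = 0.17 with an estimated correlation. Immediate early genes rose (60 of 93 rose, 15 fell and 18 neither, 61 and 16 adjusted over the list alone), with zfp36.L (3.33 ± 0.20) and btg2.S (2.42 ± 0.30). Camera on the immediate early list gave adjusted p = 1.7e-05, and adjusted p = 0.22 with an estimated correlation. Axon injury genes mostly rose (40 of 79 rose, 20 fell and 19 neither, 40 and 20 adjusted over the list alone), with ddit3.S (3.45 ± 0.34, 1.97 summed). Camera on the axon injury list gave adjusted p = 0.036, and adjusted p = 0.16 with an estimated correlation. Granzyme gzma.L (8.56 ± 0.32, 6.44 summed) and the immune checkpoint ligand cd274.L (6.22 ± 0.32) rose. In the leukocyte list apoe.L (4.03 ± 0.35, 1.1 summed) rose as well (49 of 99 rose, 8 fell and 42 neither, 46 and 8 adjusted over the list alone). For leukocyte genes camera gave adjusted p = 0.0044, and adjusted p = 0.46 with an estimated correlation. Neuronal growth genes were lower, and 3 of 59 rose, 51 fell and 5 neither (3 and 51 adjusted over the list alone), with tubb2b.L (-4.37 ± 0.19). Camera on the immature neuron list gave adjusted p = 3.9e-17, and adjusted p = 0.08 with an estimated correlation. Progenitor factors were lower too (2 of 75 rose, 52 fell and 21 neither, 2 and 52 adjusted over the list alone), with ezh2.L (-4.97 ± 0.16) and neurog2.L (-3.71 ± 0.15). The progenitor list had camera adjusted p = 4e-12, and adjusted p = 0.08 with an estimated correlation. Central neuron genes fell in part (16 of 101 rose, 57 fell and 28 neither, 16 and 58 adjusted over the list alone), with glutamatergic slc17a6.L (-2.22 ± 0.15) and camk2a.S (-2.09 ± 0.17) down. The synaptic list had camera adjusted p = 0.0044, and adjusted p = 0.21 with an estimated correlation. Bulb projection and interneuron markers fell (12 of 71 rose, 35 fell and 24 neither, 12 and 37 adjusted over the list alone), with eomes.S (-1.80 ± 0.12). The bulb marker list had camera adjusted p = 0.013, and 0.31 with an estimated correlation. Cell cycle genes were low (5 of 141 rose, 124 fell and 12 neither, 5 and 125 adjusted over the list alone), with cdk1.S (-8.20 ± 0.45). For cell cycle genes camera gave adjusted p = 4.1e-49, and adjusted p = 0.08 with an estimated correlation. Red cell genes fell (8 of 43 rose, 26 fell and 9 neither, 9 and 26 adjusted over the list alone), with hbg2.L (-7.69 ± 0.89) and slc4a1.S (-5.80 ± 0.33). Camera on the erythroid list gave adjusted p = 0.00091, and adjusted p = 0.08 with an estimated correlation. Collagen col3a1.S (-8.13 ± 0.23, -7.07 summed) fell. Ribosomal protein genes rose (106 of 107 rose, 0 fell and 1 neither, 106 and 0 adjusted over the list alone), such as rpl36.S (3.24 ± 0.43). The ribosomal list had camera adjusted p = 5.2e-32, and adjusted p = 0.25 with an estimated correlation. In the edgeR test 10180 genes were higher and 10696 lower of 31701. The majority turned with RLE factors (50.7% higher), the Wald test (50.6%) and all 39 libraries in 1 model (51.6%).

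From 2 days to 7 weeks the antiviral genes of the bulb came down and the stress genes went up (n = 3 per group). Interferon genes fell (6 of 48 rose, 36 fell and 6 neither, 6 and 36 adjusted over the list alone), with mx2.L (-4.85 ± 0.44) and ifit5.L (-3.47 ± 0.42). The interferon list had camera adjusted p = 9.5e-10, and adjusted p = 0.15 with an estimated correlation. Epithelial krt2l.S fell beside them, from 27.3, 5.85 and 63 to 0.916, 1.04 and 0.61 CPM. ATF4 response genes rose (40 of 72 rose, 4 fell and 28 neither, 41 and 5 adjusted over the list alone), among them ddit3.L (2.60 ± 0.35), chac1.L (2.44 ± 0.61) and stc2.S (3.95 ± 0.25). For ATF4 genes camera gave adjusted p = 2.4e-06, and adjusted p = 0.37 with an estimated correlation. Immediate early genes rose in parallel (58 of 93 rose, 11 fell and 24 neither, 60 and 13 adjusted over the list alone). The immediate early list had camera adjusted p = 4.7e-07, and adjusted p = 0.15 with an estimated correlation. Bulb projection and interneuron markers declined, including eomes.L (-2.33 ± 0.12) and tbr1.S (-2.12 ± 0.15) (12 of 71 rose, 43 fell and 16 neither, 12 and 44 adjusted over the list alone). For bulb marker genes camera gave adjusted p = 1.6e-08, and 0.063 with an estimated correlation. Axon growth genes declined (1 of 59 rose, 47 fell and 11 neither, 1 and 47 adjusted over the list alone). The immature neuron list had camera adjusted p = 5.8e-22, and adjusted p = 0.032 with an estimated correlation. Metabolic genes g6pc-like.1.L (4.01 ± 0.36) and hpd-like.2.L (4.09 ± 0.16) were among large increases, and collagen col1a1.L (-6.92 ± 0.59, -5.06 summed) fell from 205 to 1.68 CPM. The edgeR test gave 8115 higher and 8035 lower genes, of 31701.

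The response of the nose was set against that of the bulb at each time with the interaction term (the change of the nose minus that of the bulb, n = 3 libraries in each of 4 groups), and 5542 genes differed at 2 days, 8758 at 1 week and 12322 at 7 weeks. At 2 days the interferon genes separated the tissues: 39 of 48 responded less in the nose and 0 more (41 and 0 adjusted over the list alone, camera adjusted p = 3.5e-37, adjusted p = 0.018 with an estimated correlation), with mx2.L (-5.18 ± 0.47) and ifit5.L (-4.23 ± 0.54). Control noses held 85.6 CPM of mx2.L and 96, 137 and 111 CPM of epithelial krt15.L. The 2-day bulbs held 13.3, 9.53 and 19 CPM of mx2.L and, in the same order of libraries, 8.01, 1.45 and 16.3 CPM of krt15.L, and other tissue in these bulbs was not tested as a source. The change of olfactory transduction genes was more negative in the nose than in the bulb at 2 days (1 of 38 responded more, 18 less and 19 neither, 1 and 21 adjusted over the list alone). Camera on the olfactory transduction list gave adjusted p = 6.9e-06, and 0.44 with an estimated correlation. So it was for this list at 1 week (1 of 38 responded more, 24 less and 13 neither, 1 and 26 adjusted over the list alone), with gng13.L (-3.24 ± 0.34) and umodl1.L (-5.95 ± 0.38), the latter also because it rose in bulbs (2.05 ± 0.16). The olfactory transduction list had camera adjusted p = 8.1e-13, and 0.3 with an estimated correlation. Cell cycle genes fell more in the bulb at 2 days (33 of 144 responded more, 2 less and 109 neither, 35 and 3 adjusted over the list alone). Camera on the cell cycle list gave adjusted p = 1.9e-14, and 0.46 with an estimated correlation. At 1 week more of them differed (70 of 144 responded more, 6 less and 68 neither, 75 and 7 adjusted over the list alone), with mcm5.L (3.49 ± 0.36) and ccna2.L (3.55 ± 0.41). The cell cycle list had camera adjusted p = 2.7e-16, and 0.42 with an estimated correlation. At 1 week the difference was often negative in synaptic genes such as olfm1.L (-2.79 ± 0.25). In this list 4 of 102 responded more, 47 less and 51 neither (4 and 50 adjusted over the list alone). For synaptic genes camera gave adjusted p = 1.9e-09, and 0.45 with an estimated correlation. At 7 weeks the interferon genes differed again (0 of 48 responded more, 33 less and 15 neither, 0 and 34 adjusted over the list alone), with tapbp.S (-4.62 ± 0.75, -0.76 summed). Camera gave adjusted p = 6.1e-11, and 0.46 with an estimated correlation. By then mx2.L was down in noses (26.8, 31.6 and 40.7 CPM) and near its control level in bulbs. Granzyme gzma.L (-8.12 ± 0.39, -7.04 summed) and epithelial krt15.L (-6.69 ± 1.08) had negative differences. At 7 weeks krt15.L was down to 18.8, 8.38 and 11.4 CPM in noses, against 1.12, 0.553 and 0.522 in bulbs. In bulb cell markers the difference was more often positive than negative. Of these 28 of 74 responded more, 4 less and 42 neither (29 and 4 adjusted over the list alone). Camera on the bulb marker list gave adjusted p = 0.00021, and 0.51 with an estimated correlation. Among genes called in both tissues at 2 days, 84.8% moved the same way (3675 genes), with 85.1% at 1 week (8309 genes) and 82.8% at 7 weeks (11209 genes). Over all 30602 genes the 2 responses correlated at 0.3 at 2 days, 0.4 at 1 week and 0.42 at 7 weeks.

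Larval noses 5 h into the lower amino acid treatment were compared with control noses, to ask what this treatment changes (n = 3 per group). The protease mmp7.S (6.05 ± 0.51, 0.94 summed), neuregulin nrg3.S (5.53 ± 0.62) and mpp2.S (4.54 ± 0.38) were higher. So were cyp24a1.L (4.32 ± 0.35), piwil1.L (4.31 ± 0.17) and olfm2.S (4.27 ± 0.37), and all also rose 1 week after transection. Annotated olfactory receptor genes were higher in part (6 of 14 rose, 0 fell and 8 neither, 7 and 0 adjusted over the list alone), with or6s1.S (3.10 ± 0.51). For olfactory receptor genes camera gave adjusted p = 0.0017, and 0.38 with an estimated correlation. Of the olfactory transduction genes 5 rose and 7 fell of 38 (4 and 6 adjusted over the list alone). Proneural genes fell, with neurog1.L (-6.09 ± 0.66) and neurod4.L (-3.27 ± 0.31) (3 of 74 rose, 24 fell and 47 neither, 4 and 24 adjusted over the list alone). For progenitor genes camera gave adjusted p = 5.4e-05, and 0.41 with an estimated correlation. Tubulin tubb3.S (-2.21 ± 0.23) fell among immature neuron genes (2 of 59 rose, 32 fell and 25 neither, 3 and 32 adjusted over the list alone). For immature neuron genes camera gave adjusted p = 1.4e-07, and 0.52 with an estimated correlation. Cell cycle genes fell (2 of 144 rose, 129 fell and 13 neither, 2 and 132 adjusted over the list alone), with ccna2.S (-4.24 ± 0.62) and plk1.L (-4.13 ± 0.51). For cell cycle genes camera gave adjusted p = 4.3e-62, and 0.11 with an estimated correlation. Matrix genes fell, with col1a1.L (-4.39 ± 0.35) (7 of 91 rose, 61 fell and 23 neither, 8 and 64 adjusted over the list alone). For matrix genes camera gave adjusted p = 6.3e-22, and 0.31 with an estimated correlation. Cartilage genes fell as well, with col2a1.S (-4.70 ± 0.67) (3 of 59 rose, 39 fell and 17 neither, 4 and 40 adjusted over the list alone). For cartilage genes camera gave adjusted p = 1.2e-12, and 0.33 with an estimated correlation. Glial genes were lower (3 of 51 rose, 23 fell and 25 neither, 4 and 26 adjusted over the list alone), for example frzb.S (-2.99 ± 0.40). The glial list had camera adjusted p = 0.00034, and adjusted p = 0.31 with an estimated correlation. Skeletal muscle genes such as act3.L (-8.38 ± 2.29) and mylpf.L (-7.61 ± 2.02) were lower (1 of 81 rose, 46 fell and 34 neither, 2 and 53 adjusted over the list alone). Camera on the muscle list gave adjusted p = 5.4e-05, and adjusted p = 0.79 with an estimated correlation. The control nose libraries held 502, 28.1 and 4.75 CPM of act3.L, and without control nose library 1 the calls of act3.L (-4.94) and mylpf.L (-4.34) ended. Without this library 4 muscle genes fell and 2 rose of 82, and the list still stood lower (median -1.38, camera adjusted p = 0.007, adjusted p = 0.83 with an estimated correlation). In the edgeR test 6073 genes were higher and 6031 lower of 34151.

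At the higher dose number the noses also carried stress and detoxification transcripts (n = 3 per group). The xenobiotic-induced oxidase cyp1a1.S (8.65 ± 0.46) stood at 637 ± 197 against 1.54 ± 0.777 CPM in controls, and the heme carrier hpx.L (9.48 ± 0.63), klf9.S (6.12 ± 0.38, 4.90 summed) and slurp1l.S (5.77 ± 0.59) rose. ATF4 response genes rose, and 45 of 72 rose, 7 fell and 20 neither (46 and 7 adjusted over the list alone), with the cystine transporter slc7a11.S (3.58 ± 0.33), while phgdh.S (-2.89 ± 0.48) fell. Camera on the ATF4 list gave adjusted p = 1.4e-08, and 0.18 with an estimated correlation. Immediate early genes rose (49 of 92 rose, 1 fell and 42 neither, 49 and 2 adjusted over the list alone), with fosl1.L (4.40 ± 0.61) and atf3.L (2.85 ± 0.35). For immediate early genes camera gave adjusted p = 4.9e-07, and 0.34 with an estimated correlation. Inflammatory mediators rose (45 of 78 rose, 6 fell and 27 neither, 45 and 6 adjusted over the list alone), with csf3.L (3.88 ± 0.58). The inflammatory list had camera adjusted p = 4.4e-08, and adjusted p = 0.18 with an estimated correlation. Chaperones followed (37 of 67 rose, 7 fell and 23 neither, 38 and 7 adjusted over the list alone), with hsp90aa1.1.L (4.50 ± 0.27). The chaperone list had camera adjusted p = 4.3e-08, and adjusted p = 0.3 with an estimated correlation. Cell death and p53 genes rose in part (35 of 69 rose, 10 fell and 24 neither, 35 and 10 adjusted over the list alone), with gadd45g.S (2.73 ± 0.22). Camera on the cell death list gave adjusted p = 0.0049, and adjusted p = 0.29 with an estimated correlation. The falls of the lower dose recurred in neurog1.L (-6.67 ± 0.68), collagen col2a1.S (-7.62 ± 0.76, -6.61 summed) and cell cycle genes (1 of 144 rose, 131 fell and 12 neither, 1 and 131 adjusted over the list alone). Camera on the cell cycle list gave adjusted p = 3.7e-44, and adjusted p = 0.18 with an estimated correlation. Muscle genes fell again (1 of 81 rose, 59 fell and 21 neither, 1 and 61 adjusted over the list alone), with act3.L (-9.54 ± 2.45). The muscle list had camera adjusted p = 2.1e-05, and adjusted p = 0.65 with an estimated correlation. Without control nose library 1 act3.L was at -6.10 and 14 muscle genes fell and 1 rose of 82, with the list still lower (median -1.74, camera adjusted p = 0.00076, adjusted p = 0.66 with an estimated correlation). The edgeR test gave 9168 higher and 7747 lower genes, of 34151. With all 39 libraries in 1 model the majority turned, to 7114 higher and 8596 lower (45.3% higher). Log2 fold changes of both doses, each against the same controls, correlated at 0.8 across 34151 genes (covariance 0.97, and genes are not independent replicates). They shared 4785 higher and 4145 lower genes, beside 1630 and 1368 for independent lists. In 20 simulated pairs of unchanged groups sharing the controls the covariance was at most 0.06, against 0.9 in the 9 libraries fitted alone.

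**Figure D3:**
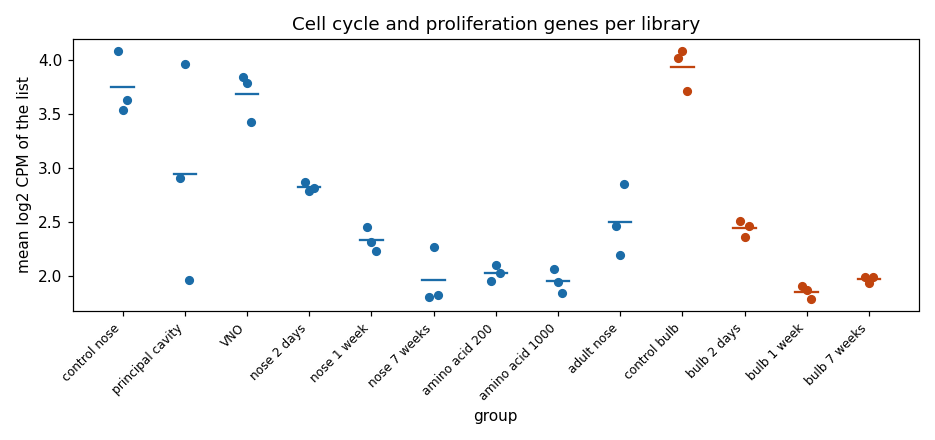
Mean log2 CPM over the members of the cell cycle list (y axis) in all 39 libraries by group (x axis). The lowest control nose stood at 3.54, and transected and amino acid noses reached at most 2.87.

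**Figure D4:**
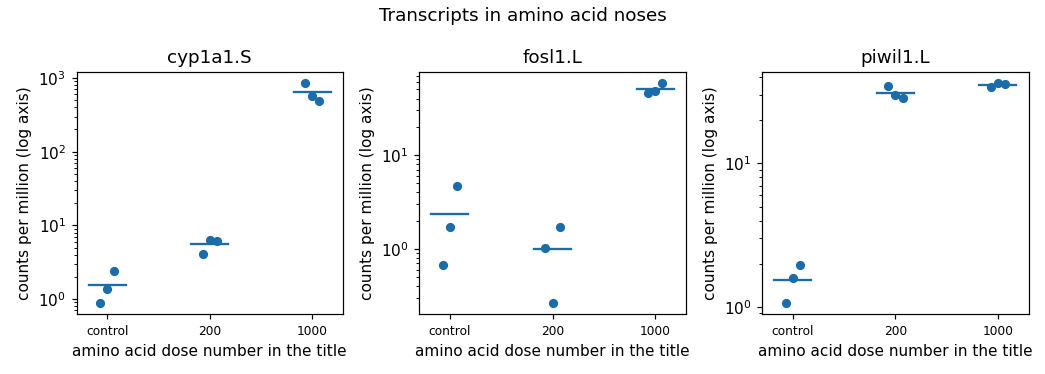
CPM (y axes, logarithmic) of cyp1a1.S, fosl1.L and piwil1.L in larval noses of controls and of the amino acid doses 200 and 1000 (x axes). At 1 week after transection piwil1.L rose too. Points are the 3 libraries of each group and bars their mean, which for cyp1a1.S was 1.54, 5.53 and 637.

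When the amino acid groups were set against each other, activity and stress genes were higher at the higher dose number (n = 3 per group). Immediate early genes rose (56 of 92 rose, 2 fell and 34 neither, 60 and 2 adjusted over the list alone), with egr3.S (6.37 ± 0.49), fosl1.L (5.69 ± 0.66) and crem.L (3.44 ± 0.56). Camera on the immediate early list gave adjusted p = 1e-18, and 0.2 with an estimated correlation. ATF4 response genes rose (40 of 72 rose, 3 fell and 29 neither, 45 and 5 adjusted over the list alone), with slc7a11.S (4.97 ± 0.35) and the glutamine transporter slc1a5.S (3.11 ± 0.40). The ATF4 list had camera adjusted p = 2.3e-13, and 0.11 with an estimated correlation. Chaperones rose too (36 of 67 rose, 1 fell and 30 neither, 39 and 1 adjusted over the list alone), including bag3.L (4.34 ± 0.41) and hsph1.S (2.99 ± 0.27). For chaperone genes camera gave adjusted p = 1e-18, and 0.15 with an estimated correlation. Axon injury genes were higher (34 of 82 rose, 6 fell and 42 neither, 37 and 7 adjusted over the list alone), with socs3.L (3.09 ± 0.34). The axon injury list had camera adjusted p = 5.3e-08, and 0.11 with an estimated correlation. Cell death genes were higher (30 of 69 rose, 1 fell and 38 neither, 33 and 1 adjusted over the list alone), with tnfrsf10b.L (2.55 ± 0.27). The cell death list had camera adjusted p = 1.9e-06, and 0.12 with an estimated correlation. Inflammatory mediators were higher (40 of 78 rose, 5 fell and 33 neither, 43 and 5 adjusted over the list alone), with the collagenase mmp1.S (3.80 ± 0.54). For inflammatory genes camera gave adjusted p = 6.4e-10, and 0.18 with an estimated correlation. Other increases were cyp1a1.S (6.86 ± 0.42), odam.L (6.95 ± 1.33), stc1.S (5.61 ± 0.46, 3.83 summed) and adamts4.L (5.51 ± 0.53). Olfactory transduction genes were slightly lower (1 of 38 rose, 6 fell and 31 neither, 1 and 6 adjusted over the list alone), with the channel subunit cngb1.L (-0.90 ± 0.20), and so were col2a1.S (-2.92 ± 0.62) and ccdc3-like.2.S (-3.02 ± 0.22). For olfactory transduction genes camera gave adjusted p = 0.042, and 0.81 with an estimated correlation. By the edgeR test 5588 genes were higher and 3605 lower of 34151, and the count of 9193 fell to 5952 without library 3 of the higher dose. RLE factors shifted the median of all genes by -0.058 log2 and brought the share of called genes that were higher from 60.8% to 51.7%. With all 39 libraries in 1 model 3715 were higher and 4323 lower (46.2% higher), so which direction holds the majority is not settled.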

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

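The tests of the 3 patterns weighed here were chosen after the results were seen, whereas the interaction tests and the regrouping of libraries were planned. Responses that differed between nose and bulb were measured directly with the interaction term: 5542 genes at 2 days, 8758 at 1 week and 12322 at 7 weeks. At 2 days sppl2b.L differed by -9.52 ± 0.38 (-2.20 with homeologs summed) and mx2.L by -5.18 on the log2 scale, the first with the larger rise in the bulb and the second with a rise called in the bulb alone. For each time, 100 regroupings of the 12 libraries of control and transected tissue were drawn, the real one included. At 2 days the real grouping called 8646 genes in a fit of these libraries alone, and 4 of 100 called as many. At 1 week it called 11955 and 2 of 100 did so, and at 7 weeks 7381 and 2 of 100. The highest other counts, 15552, 19577 and 16313, came from groupings that keep the true division of 1 tissue and so carry its transection effect, which points to the structure of the samples. Groupings mixed in both tissues place that effect in the residual spread and decide nothing, and of those that keep 1 tissue 3 of 22, 1 of 18 and 1 of 16 reached the real count, so these regroupings do not settle whether chance division plays a part.

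Transcripts lower in transected noses were also lower in amino acid noses, which the labels do not give as transected. The comparisons of amino acid 200 against controls and of 7 weeks against 2 days in noses share no library. Of genes called in both, 87.8% moved the same way (2843 higher and 2772 lower), although over all 34151 genes the correlation was only 0.2. Both groups of the second comparison were transected, so it follows time after transection. This share therefore cannot decide whether nerve transection alone lowers transcripts. Control noses did not stand alone with a high cell cycle level, since 5 of 6 principal cavity and VNO libraries lay above every treated nose library (highest 2.87). With bulbs in place of noses at 7 weeks against 2 days the share was 85.7%, but adult against larval noses shared only 58.9% with noses at 7 weeks against 2 days (correlation 0.09). Older larvae in the later groups therefore cannot be told apart from the treatments or the season of collection, since the labels give no stage for each larval group.

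Muscle transcripts were lower in amino acid noses than in controls. In noses at 7 weeks, without amino acid, their median was -1.79 against controls and -1.6 against 2 days. Control noses ranged over 2.33 in mean muscle level (1.4 to 3.73 log2 CPM), beyond the 1.38 gap from their mean to amino acid noses. Without control nose library 1 the range was 0.35, the gap 0.66 and the list medians -1.38 and -1.74 at the doses 200 and 1000. The lowest control (1.4) lay above the highest amino acid nose (1.02). Uneven muscle in the tissue cannot be told apart from a treatment effect with 3 controls and no record of the muscle dissected. No biological explanation was tested.

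Stress transcripts were higher at the 1000 than at the 200 amino acid dose. Scaling is not tested by the immediate early median, 1.23 with TMM and 1.17 with RLE factors, which shift all genes alike. Tissue handling before freezing cannot be told apart from the dose, since 58 immediate early genes rose also in bulbs between 2 days and 7 weeks, without any amino acid, and handling times are not in the labels. A response to the higher dose stays open as the biological explanation.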

How the results depend on the processing

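The joint omission of principal cavity library 3 and VNO library 1, and the muscle list without control nose library 1, were chosen after the data were seen, and the other alternatives were planned. RLE factors, the DESeq2 Wald test, no low-count filter, summed homeologs and all 39 libraries in 1 model left the count of called genes within 1.5 times the reported one in all 17 comparisons, except principal cavity against VNO, where 1 model for all libraries gave 13486 genes in place of 4768, with the cause not tested beyond the larger number of libraries that set the spread. Without 1 library at a time the counts ran from 1999 (without principal cavity library 1) to 6053 (without VNO library 1) for these chambers, with 2646 without principal cavity library 3 and 2467 without VNO library 2. Omitting both principal cavity library 3 and VNO library 1 gave 4840, and 73.4% of the reported genes were called again.

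For noses at 2 days the range was 3888 (without its library 3) to 7235, with 4336 without control nose library 3 and 4411 without nose 2 days library 2. For amino acid 1000 against 200 it was 5952 (without library 3 of the higher dose) to 7995. The fall in these counts follows fewer libraries, and why these libraries count most was not tested. The other ranges were 13219 to 15082 for adult noses, 24535 to 25189 for noses against bulbs, 11017 to 12881 for noses at 1 week, 14663 to 16644 at 7 weeks, 11334 to 14696 for noses at 7 weeks against 2 days, 11361 to 13956, 15119 to 17051 and 18982 to 22378 for bulbs at 2 days, 1 week and 7 weeks, 13424 to 17815 for bulbs at 7 weeks against 2 days, 8980 to 11817 and 14334 to 15444 for the amino acid doses 200 and 1000, and 3881 to 5549, 6782 to 8627 and 10452 to 12977 for the interactions.

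Of 261 list results past the threshold, 13 stayed past it with an estimated correlation and 248 did not, 219 with fry (which added 59), and 260 with RLE factors (which added 2), and none turned direction. Without control nose library 1, 4 and 14 muscle genes fell at the doses 200 and 1000, in place of 46 and 59. The list stayed lower. The correlation between the doses was 0.8 with and without the 5 CPM minimum. Of 270 values of named genes past the threshold, 270 stayed past it with RLE factors, the Wald test, no filter and 1 model for all libraries, but examples were picked in part for holding under these alternatives and without single libraries, so this share says little about other genes. With homeologs summed, 35 moved by more than 1 on the log2 scale, and 19 did so without 1 library, of 1686 such values, with the cause not tested. Beside those given with the results these were hbg2.L (-9.70) and cdk1.S (-9.64) in bulbs and hbg2.L (-7.49) and gad1.1.L (4.83) in noses at 7 weeks, sds.S (7.29), hpx.L (10.65), neurog1.L (-8.51), muc19.L (4.11 and 6.88), and, between nose and bulb, neurod6.L (-15.42), neurod2.S (-14.75) and npy.S (-14.70). Principal cavity and VNO titles alternate in library number (11 and 12, 13 and 14, 15 and 16), without a word on common animals. The replicate block planned for them takes column replicates 1 to 3 for these numbers in order, an assumption, and gave 4854 genes in place of 4768, with 84.5% of the reported genes called again. Deviations from the group means correlated at -0.08, 0.11 and 0.24 between same-numbered libraries, and not every library correlated best with its own number (up to 0.17 for principal cavity 2 and VNO 1), so no pairing was taken. The majority direction also turned with 1 model for all libraries in the interactions at 2 days and 1 week (54% and 52% higher), with the cause not tested. It turned with the Wald test at the dose 1000 against 200 (49.9% higher), and with some alternatives in adult noses, bulbs at 7 weeks against 2 days and the dose 200, where the counts were nearly even. Depth (from 25.82 M reads) limits the calls at low counts, and with 3 libraries per group 2-fold changes were recovered in 56.9% of simulated genes in noses at 2 days.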

Other observations

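The genes of the first 2 paragraphs and the library values were picked after the data were seen, and the regroupings and the shared-control test were planned. The protease gene sppl2b.L was nearly absent from control bulbs (0.135, 0.361 and 0.206 CPM) and abundant in every other group. It stood at 314, 373 and 268 CPM in bulbs at 2 days, 582, 539 and 486 at 1 week and 356, 595 and 450 at 7 weeks. In noses it was at 65.3, 96.5 and 80.6 CPM in controls and 280, 254 and 251 at 1 week, so near-absence was seen in control bulbs alone. The rise of sppl2b.L in bulbs at 2 days was 10.33 ± 0.32 for this copy and 2.77 with both homeologs summed, so its other copy was counted in control bulbs already.

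The thyroid hormone and glucocorticoid target klf9.L was higher than in controls in adult noses, in noses at 1 week and 7 weeks, in bulbs at 7 weeks and in amino acid noses. Control noses held 16.4, 10.6 and 7.94 CPM and adult noses 58.4, 50.4 and 72.3, noses at 7 weeks 176, 132 and 375, and noses at the amino acid doses 200 and 1000 73.5, 63.5 and 57.6, and 398, 310 and 322. Bulbs at 7 weeks held 95.9, 37.8 and 101 CPM against 9.61, 7.92 and 10 in control bulbs. Noses at 1 week held 20.9, 38.6 and 40.1 CPM and at 2 days 16.5, 19.2 and 17.9, and bulbs held 7.4, 8.57 and 7.04 CPM at 2 days and 10, 14.3 and 14.7 at 1 week. The epithelial gene krt15.L was at 81.8, 0.726 and 1.91 CPM in the VNO libraries.

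In every comparison of 3 against 3 libraries the 10 possible divisions are too few for a share under 0.05. These fits held only the compared libraries, so counts differ from those above, except for principal cavity against VNO. The real division called 14419 genes for adult noses, 4768 for principal cavity against VNO and 25091 for noses against bulbs. For noses at 2 days, 1 week and 7 weeks it called 6270, 13039 and 8563, and 7151 at 7 weeks against 2 days. In the same order bulbs gave 17978, 20753, 17659 and 12593. The amino acid doses 200, 1000 and 1000 against 200 gave 12544, 17120 and 14125. The highest other division called 1 gene for bulbs at 2 days and 0 elsewhere.

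Amino acid noses of both doses were set against the same control libraries. In 20 simulated pairs of unchanged groups sharing the controls the correlation of log2 fold changes reached 0.53 at most, against 0.81 in the 9 measured libraries, and the covariance 0.06 against 0.9. Shared control libraries alone therefore leave part of the common change unexplained, and genes are not independent replicates.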
